A study of Arabidopsis thaliana with 18 samples.

How the data were processed

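RNA of developing seeds of Arabidopsis thaliana was measured on Affymetrix arrays of 22810 probe sets, a probe set being a group of short probes that report on 1 transcript or a few similar ones. Per the labels' protocols, plants of the accessions Col-0 and C24 were grown with 16 h of light in 2 experiments, flowers were tagged on the day they opened, and siliques (the seed pods) were taken 8 or 9, 10 or 11, and 12 or 13 days later. Each replicate was a pool of seeds dissected from 48 siliques, 8 from each of 6 plants, with plants of both experiments in every pool, and RNA was isolated from 200 mg of seeds. The RNA was labelled with biotin and processed by a service provider. There were 18 arrays in 6 groups of 3. The labels call the pools biological replicates, but pools of a group could share plants, so p-values measure the spread between pools only.

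The deposited values are on a log2 scale and were made with RMA (background correction, quantile normalization and summary per probe set), per the submitters' processing notes; the version is not given in the sources used here. RMA brings the arrays to nearly 1 distribution, so a change of all transcripts together would not be seen, and it compresses fold changes near the floor of the scale and near its top. Array medians lay between 5.84 and 5.96. An array has no read depth; the number of arrays limits the precision.

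Accession and stage were taken from the sample titles, with which the descriptions and the other characteristics matched. The source name field gives the other accession in all 18 samples. The titles were used, and a check on the arrays is given after the results. After 64 control probe sets were left out, 22746 were tested. The gene table of the platform lists 14016 of these, 13513 (59.4%) with 1 gene and 503 with several, and it does not list the remaining 8730, which stay unnamed here. A locus of the assembly TAIR10.1 was found for 13436 probe sets, or 13286 loci. Only probe sets with 1 gene are named.

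A linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 8.331 prior degrees of freedom), because 3 arrays per group alone leave few degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. Adjusted p-values of single genes come from this fit, and SE is the standard error of the log2 difference. There were 11 comparisons, namely C24 minus Col-0 at each of the 3 stages and averaged over them, the 3 differences between stages within each accession, and the difference between the accessions in their change from 8-9 to 12-13 d, called the interaction. A positive accession difference means a higher signal in C24.

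The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. By that rule, the text names up to 8 probe sets with the highest and 8 with the lowest log2 differences in each accession comparison at a stage, in the change from 8-9 to 12-13 d of each accession and in the interaction, if they were called, have 1 gene and, except for the interaction, have groups that do not overlap. It also takes the 2 highest and the 2 lowest called members of each list, or the member with the smallest p where none was called, and it allows a gene named in a comparison to be followed in the others. The rule also asked for FLC, FRI, LEC1, LEC2, FUS3, ABI3, WRI1 and DOG1, which have no listed probe set and were not analysed here.

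The 22 lists hold 428 loci, of which 90 were measured by a listed probe set. The lists of late embryogenesis abundant (LEA) proteins, plastid fatty acid synthesis, photosynthesis, reference genes, endosperm markers, heat shock proteins, sucrose and starch metabolism, glucosinolate metabolism, cell division, oil body proteins, seed maturation regulators and seed coat flavonoids have 3 or more measured members and were tested with camera, at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over these 12 lists. Lists with 1 or 2 measured members are given as values. Coverage was 22 of 30 for LEA proteins, 10 of 34 for fatty acid synthesis, 8 of 43 for photosynthesis and 4 of 37 for cell division. It was 3 of 17 for maturation regulators, 3 of 19 for flavonoids and 2 of 10 for storage proteins. Statements on a list cover its measured members only. Another 5 lists had no measured member and were not analysed here. Beside calls over all probe sets, calls adjusted over the list alone are given.

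Signals were also scaled to the 8 measured reference genes. This moved all probe sets by a log2 of -0.01, -0.11 and -0.08 in C24 minus Col-0 at the 3 stages and by -0.07 in their average. The change from 8-9 to 12-13 d moved by 0.22 in Col-0 and 0.15 in C24, the steps by 0.11 and 0.10 in Col-0 and by 0.01 and 0.14 in C24, and the interaction by -0.06. Other alternatives were quantile normalization, leaving out dim probe sets whose highest group mean is under 6, 1 probe set per gene, leaving out probe sets shared by similar transcripts, a trend and robust variance, array weights, a replicate block, a 2-fold minimum, fitting only the groups compared, and leaving out each array in turn.

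The fit was tested on 10 simulated data sets of 22746 probe sets with known changes. For the accession difference at 10-11 d it recovered 62.4% of changes of 0.5 on the log2 scale, 98.0% of changes of 1 and 100% of changes of 2, with 5.56% false calls. For the change in Col-0 from 8-9 to 12-13 d it recovered 65.2% of changes of 0.5 and 96.8% of changes of 1, with 5.29% false calls. For the interaction it recovered 24.2% of changes of 0.5 and 90.6% of changes of 1, with 5.07% false calls. A shifted list of 20 members was called in 10 of 10 simulated data sets and an unchanged list in 0 of 10. All members of the shifted list moved by 0.5, and simulated probe sets varied independently. The simulation therefore does not show how camera treats lists with few or correlated members.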

Results

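Transcript levels were measured in seeds of the Arabidopsis accessions Col-0, the reference accession of the species, and C24, a natural accession. Seeds were taken 8-9, 10-11 and 12-13 days after flower opening, with 3 pools of seeds per accession and stage. The design compares the accessions at the same stage and the stages within each accession. Arrays of the same group correlated with Pearson's r of 0.993 to 0.997 over all probe sets and arrays of different groups with r of 0.882 to 0.985, and no 2 arrays were identical. The median SD of a probe set within a group was 0.0924 to 0.132 on the log2 scale. The first principal component held 70.6% of the variance and followed stage, and the second held 11.6% and separated the accessions.

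**Figure D1:**
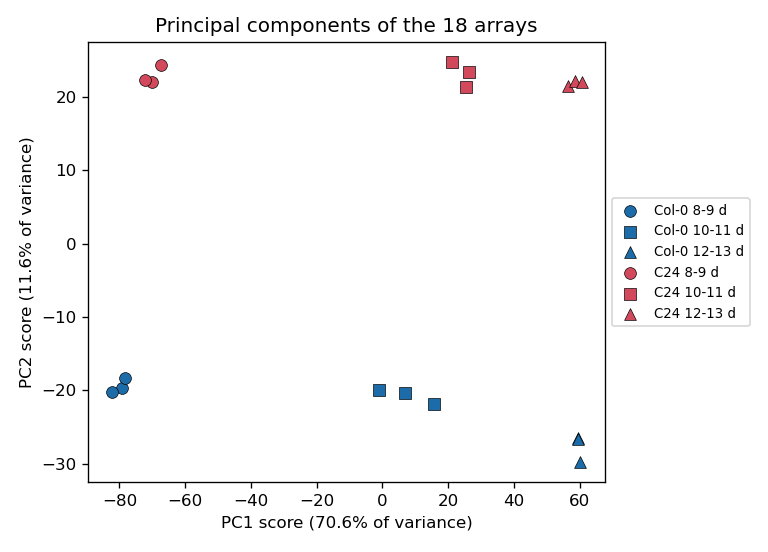
Scores of the 18 arrays on the first 2 principal components, with blue for Col-0, red for C24 and a marker shape for each stage. Stages lie apart along the first component (70.6% of the variance), and all C24 arrays lie above all Col-0 arrays on the second (11.6%).

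In Col-0 seeds, AT4G38080 rose from 8-9 to 12-13 d by a log2 of 8.82 (SE 0.14), from 3.93 ± 0.17 to 12.75 ± 0.10 (SD, n = 3). It started near the floor of the scale, where RMA compresses differences, so this size and the order of such genes are not exact. The pectin methylesterase family gene AT3G60730 rose by 8.26 (SE 0.18), AT1G19900 by 8.12 (SE 0.19), CYP78A9, a cytochrome P450, by 8.03 (SE 0.14), and AT2G18370, of the lipid transfer protein family, by 8.01 (SE 0.49). GILT, a thiol reductase family gene, fell by 8.55 (SE 0.36), from 13.68 ± 0.10 to 5.12 ± 0.58 (SD, n = 3). ATPMEPCRD, a pectin methylesterase, fell by 6.98 (SE 0.24), JMT, which methylates jasmonic acid, by 6.42 (SE 0.20), AT4G15750, of the pectin methylesterase inhibitor family, by 6.13 (SE 0.21), and the peroxidase gene AT5G15180 fell by 5.55 (SE 0.15). All of these had limma adjusted p-values of 7.18e-12 or lower. Across the array 12330 of 22746 probe sets (54.2%) were called, 6060 higher and 6270 lower at 12-13 d, and 1590 rose and 1853 fell at least 2-fold. Scaled to the reference genes, 9821 were higher and 4171 lower, so the balance of direction rests on the scaling.

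In C24 the change over the same interval was led by the same 2 risers, AT4G38080 with 8.26 (SE 0.14) and AT3G60730 with 8.10 (SE 0.18), followed by the peroxidase gene AT1G68850 with 7.93 (SE 0.12) and AT1G14940 with 7.84 (SE 0.23). GILT fell by 8.68 (SE 0.36) and ATPMEPCRD by 7.07 (SE 0.24), followed by AT5G60630 with -5.69 (SE 0.16), AT5G51950 with -5.57 (SE 0.17) and JMT with -5.45 (SE 0.20). Adjusted p-values in limma were 6.91e-17 or lower for the 4 risers, and 1.4e-14 for GILT. In C24, 12211 probe sets were called, 5954 higher and 6257 lower, against 8140 higher and 4488 lower when scaled to the reference genes. The changes of the accessions correlated across probe sets, which are not independent replicates, with Pearson's r of 0.925 and Spearman's rho of 0.856, and the slope of C24 on Col-0 was 0.857. Both accessions rose in 4400 probe sets, where independent lists would share 1586, and both fell in 5153, where independent lists would share 1725. Opposite directions were called in 132.

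**Figure D2:**
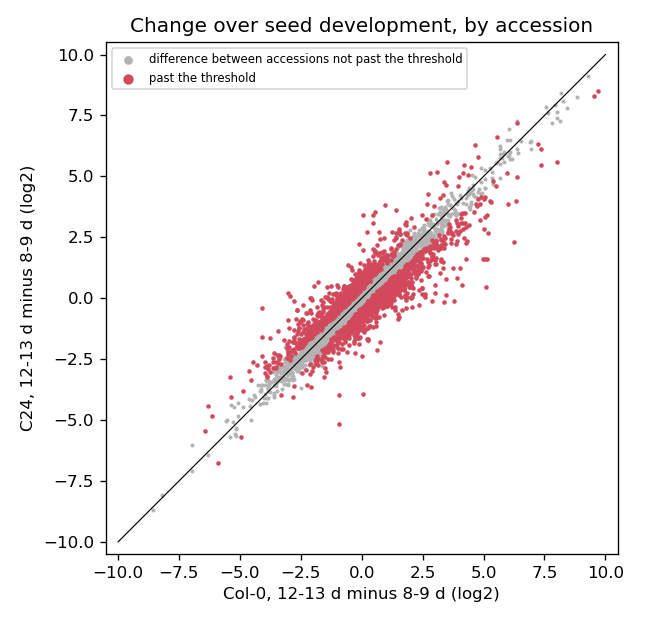
Each point is a probe set, with its log2 change from 8-9 to 12-13 d in Col-0 on the horizontal axis and in C24 on the vertical axis. Red points are the 2080 probe sets called for the difference between the changes, and the line marks equal change. Most probe sets lie along the line (Pearson's r of 0.925).

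LEA proteins, which accumulate in seeds late in development, rose as a group over the same interval. In Col-0, 17 of 22 measured members rose, 0 fell and 5 were not called, and in C24 19 rose, 0 fell and 3 were not called, with the same counts when adjusted over the list alone. AT3G15670 rose by a log2 of 6.89 in Col-0 and 6.42 in C24 (SE 0.21 for both), AT3G02480 by 5.31 in Col-0 (SE 0.24) and AT3G17520 by 4.16 in C24 (SE 0.19). The camera adjusted p was 9.12e-09 in Col-0 and 1.92e-08 in C24, and the adjusted p = 0.0525 and 0.0403 with an estimated correlation. All 3 measured seed maturation regulators rose in both accessions, the MADS box gene AGL67 by 5.06 in Col-0 and 4.54 in C24, EEL by 1.19 and 1.14 and BZIP53 by 0.83 and 0.88. The count was 3 adjusted over the list alone in each accession, with camera adjusted p of 0.00375 and 0.00321 and adjusted p = 0.0699 and 0.0744 with an estimated correlation. Of the storage protein genes, the cruciferin family gene AT1G03890 rose by 4.18 in Col-0 and 2.45 in C24 (SE 0.33), and the vicilin family gene PAP85 by 1.80 and 1.48 (SE 0.12). Both of the 2 measured members rose in both accessions, also when adjusted over the list alone.

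**Figure D3:**
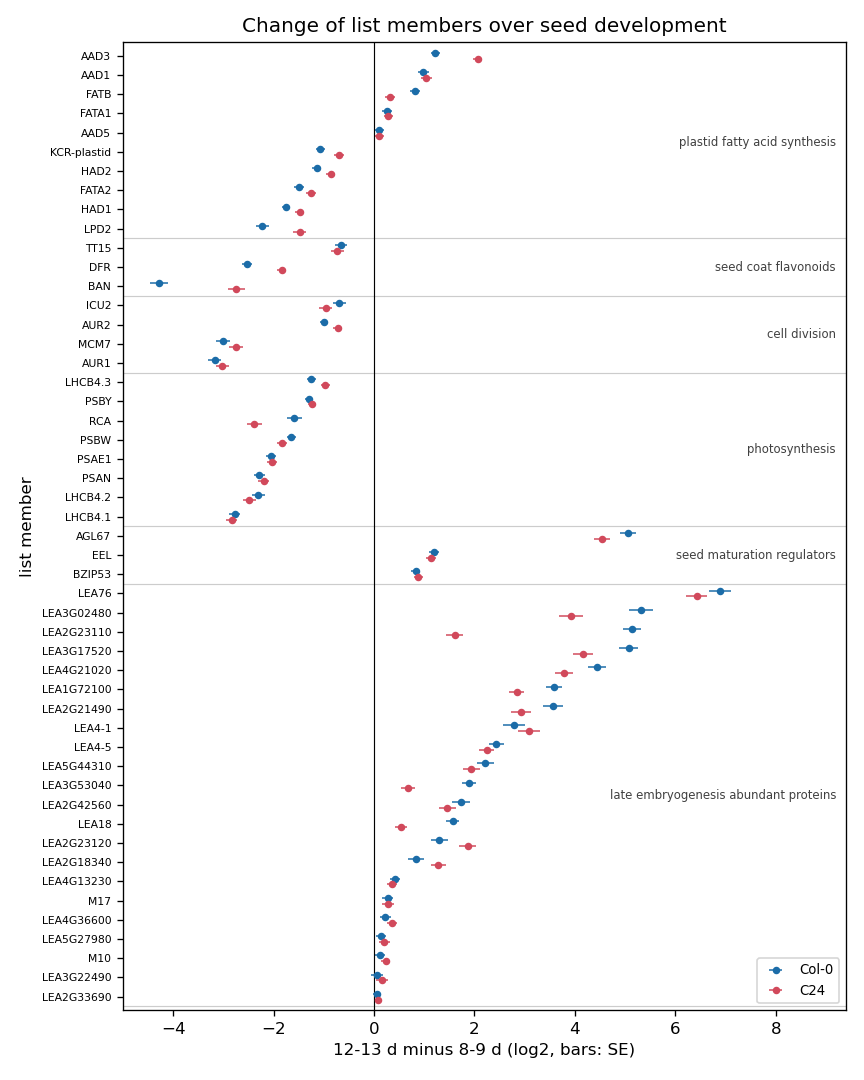
Log2 change from 8-9 to 12-13 d (horizontal axis) of each measured member of 6 gene lists, with Col-0 in blue, C24 in red and bars for SE. LEA genes and maturation regulators lie at or above 0, with AT3G15670 (shown as LEA76) at 6.89 in Col-0, and photosynthesis, cell division and flavonoid genes lie below 0, with BAN at -4.29 in Col-0.

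Photosynthesis genes fell in both accessions. All 8 measured members were lower at 12-13 d in Col-0 and in C24, and 8 when adjusted over the list alone. LHCB4.1, a light-harvesting protein of photosystem II, fell by a log2 of 2.78 in Col-0 and 2.84 in C24 (SE 0.10), and LHCB4.2 changed by -2.31 and -2.48 (SE 0.13). The camera adjusted p was 5.02e-07 and 1.11e-07, with adjusted p = 0.0525 and 0.0403 with an estimated correlation. The 4 measured cell division genes fell as well, 4 adjusted over the list alone in each accession. The mitotic kinase gene AUR1 changed by -3.18 in Col-0 and -3.02 in C24 (SE 0.13), and PRL, a subunit of the replicative helicase, by -3.01 and -2.74 (SE 0.14). Their camera adjusted p was 0.00195 and 0.00138, with adjusted p = 0.0676 and 0.0744 with an estimated correlation.

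All 3 measured seed coat flavonoid genes fell in both accessions, 3 adjusted over the list alone. BAN, the anthocyanidin reductase of tannin synthesis, fell by a log2 of 4.29 in Col-0 and 2.74 in C24 (SE 0.17), DFR, dihydroflavonol reductase, by 2.53 and 1.84 (SE 0.10), and UGT80B1, a sterol glucosyltransferase, by 0.66 and 0.73 (SE 0.12). The camera adjusted p was 0.00375 and 0.00584, with adjusted p = 0.0676 and 0.0744 with an estimated correlation. Both of the 2 measured seed coat mucilage genes fell, the peroxidase gene AT3G50990 by 3.44 in Col-0 and 1.35 in C24 (SE 0.16) and the subtilase ARA12 by 2.05 and 1.84 (SE 0.12). Of the glucosinolate genes 4 of 5 rose and 1 was not called in each accession, 4 adjusted over the list alone. The transporter GTR2 rose by 2.47 and 2.22 (SE 0.13), and BCAT4, of methionine chain elongation, by 1.85 and 1.22 (SE 0.17), with camera adjusted p of 0.00411 in Col-0 and 0.0193 in C24 and adjusted p = 0.0676 and 0.116 with an estimated correlation.

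Other lists moved in both directions or little. Of 10 genes of plastid fatty acid synthesis 4 rose, 5 fell and 1 was not called in each accession, as when adjusted over the list alone (camera adjusted p of 0.352 in Col-0 and 0.424 in C24). The stearoyl-ACP desaturase family gene AT5G16230 rose by a log2 of 1.22 in Col-0 and 2.07 in C24 (SE 0.09), and AT4G16155, a plastid dihydrolipoamide dehydrogenase, fell by 2.22 and 1.48 (SE 0.13). Of 5 sucrose and starch genes 2 rose and 3 fell in Col-0 and 1 rose and 3 fell in C24 (0.352 and 0.168), also when adjusted over the list alone. The sugar transporter SAG29 rose by 1.17 and 0.97 (SE 0.09), and APL4, of starch synthesis, fell by 1.39 and 1.96 (SE 0.13). Of 3 oil body genes, AT5G16460, a seipin family gene, rose by 2.74 in Col-0 and 2.65 in C24 (SE 0.14). OLEO3, an oleosin, was at -0.35 in Col-0 (SE 0.07, adjusted p = 0.000416), and when scaled to the reference genes at -0.13 (adjusted p = 0.254). The list's camera adjusted p was 0.48 in Col-0 and 0.319 in C24, with 1 higher and 1 lower in Col-0 and 1 higher and 0 lower in C24, also when adjusted over the list alone. Of 5 small heat shock proteins 1 rose in Col-0 and 2 in C24, as when adjusted over the list alone, and AT5G37670 rose by 2.34 and 1.24 (SE 0.10; camera adjusted p of 0.348 and 0.235).

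Few markers of single tissues were measured. Of 25 endosperm markers in the list 6 were measured. Of these 0 were called by limma in any of the 11 comparisons, over all probe sets or adjusted over the list alone. In each comparison 0 or 1 had an unadjusted limma p under 0.05. Their camera adjusted p was 0.863 for the change in Col-0 and 0.629 in C24. Whether these markers were expressed at these stages was not examined, so this does not show that the endosperm did not change. The 2 measured silique wall markers had median log2 changes of -0.01 in Col-0 and -0.13 in C24, with 1 called higher in each and 1 lower in C24. The 1 measured gene of storage lipid assembly rose by 0.60 and 0.70, and the 1 of salicylic acid defence was at -0.13 in Col-0, not called, and at -0.34 in C24, called. Before any scaling to them, of the 8 reference genes 4 fell in Col-0 and 3 in C24, with 0 risen, also when adjusted over the list alone (camera adjusted p of 0.169 and 0.319). The log2 difference between 3' and 5' probe sets of the actin control, a sign of RNA quality, fell with stage, from 1.84 to 0.93 in Col-0 and from 0.85 to -0.28 in C24. That of the ubiquitin control went from 0.88 to 0.44 and from 0.94 to 0.77, and that of GAPDH from 0.89 to 1.77 and from 0.94 to 1.19.

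Divided into steps, AT4G38080 rose early, by a log2 of 8.49 from 8-9 to 10-11 d in Col-0 and 8.63 in C24, with 0.33 and -0.36 in the later step, neither called. AT1G14940 rose more in the later step in both accessions, by 5.23 in Col-0 and 4.49 in C24, after 2.32 and 3.34 (SE 0.23). LEA genes rose in both steps, with 13 and 15 of 22 risen in Col-0 and 13 in each step in C24 (15 and 14 in the later step when adjusted over the list alone). All 8 photosynthesis genes fell from 10-11 to 12-13 d in both accessions, with camera adjusted p of 4.19e-10 in Col-0 and 1.38e-11 in C24, which held with an estimated correlation (adjusted p = 0.027 and 0.0162). BAN changed by -2.94 in the first step in Col-0 and by -2.31 in C24 (SE 0.17), and by -1.35 in the second in Col-0. In Col-0 8403 probe sets were called in the first step, 3828 higher and 4575 lower, and 7114 in the second, 3366 higher and 3748 lower. In C24 10058 were called in the first, 4707 higher and 5351 lower, and 5022 in the second, 2222 higher and 2800 lower. Scaled to the reference genes the splits were 4693 higher and 2970 lower, then 4056 and 2288, in Col-0, and in the second step of C24 3451 and 1435.

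The lists are given here for each step, and differences between the steps were not tested. Cell division genes fell in 4 of 4 in both accessions from 8-9 to 10-11 d (camera adjusted p of 0.000155 in Col-0 and 0.000213 in C24, and adjusted p = 0.0419 and 0.0539 with an estimated correlation), while 2 of 4 fell in the second step in each (0.176 and 0.525). Flavonoid genes fell in 3 of 3 in both accessions in the first step (0.000314 in Col-0 and 0.0026 in C24, adjusted p = 0.0419 and 0.0539 with an estimated correlation), and in the second 1 fell in Col-0 and 0 in C24 (0.193 and 0.708). AT1G03890 rose by a log2 of 4.06 in Col-0 and 2.44 in C24 in the first step and was at 0.11 and 0.01 in the second, not called. Maturation regulators rose in 3 of 3 in Col-0 and 2 of 3 in C24 in the first step (0.000389 and 0.00937, adjusted p = 0.0419 and 0.113 with an estimated correlation), and in the second 2 rose in each (0.176 and 0.0102, adjusted p = 0.175 in C24 with an estimated correlation). Of the glucosinolate genes 4 of 5 rose in Col-0 (5 adjusted over the list alone) and 5 in C24 in the first step (0.00134 and 0.00406, adjusted p = 0.0419 and 0.0621 with an estimated correlation), and in the second 3 rose and 1 fell in Col-0 and 2 rose and 1 fell in C24 (0.178 and 0.708). Of the fatty acid genes 2 rose and 7 fell in the second step in Col-0, as when adjusted over the list alone (0.00317, adjusted p = 0.278 with an estimated correlation). In C24 2 rose and 3 fell (0.525), or 2 and 5 when adjusted over the list alone. LEA genes had camera adjusted p-values of 3.42e-07 and 2.27e-09 in the steps of Col-0 and 4.6e-06 and 1.18e-08 in those of C24 (adjusted p = 0.0419, 0.0321, 0.0539 and 0.0417 with an estimated correlation). In the first step photosynthesis genes fell in 7 of 8 in Col-0 and 8 in C24 (0.000155 and 1.59e-05, adjusted p = 0.067 and 0.0539 with an estimated correlation).

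At 8-9 d, AT4G29200 had a log2 signal higher in C24 by 5.79 (SE 0.19), at 10.47 ± 0.09 against 4.68 ± 0.32 in Col-0 (SD, n = 3). The exostosin family gene AT5G41250 was higher by 5.47 (SE 0.20), AT1G62210 by 4.24 (SE 0.36), the cathepsin B-like protease gene AT1G02300 by 4.13 (SE 0.15) and AT1G50290 by 4.04 (SE 0.14). AT1G62210 varied in Col-0, with an SD of 1.37. Lower in C24 were AT2G15325 with -4.58 (SE 0.35), AT5G38180, of the lipid transfer and 2S albumin family, with -4.53 (SE 0.54), AT2G32190 with -3.85 (SE 0.16), AT1G23960 with -3.46 (SE 0.17) and the acyltransferase family gene AT4G15390 with -3.46 (SE 0.19). AT5G38180 had an SD of 2.01 in C24. All 10 had limma adjusted p-values of 2.62e-06 or lower. Of 22746 probe sets 4418 were called, 2666 higher and 1752 lower in C24, with 246 and 253 at least 2-fold.

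Of the storage protein genes at 8-9 d, AT1G03890 was higher in C24 by a log2 of 1.83 (SE 0.33, adjusted p = 0.000405) and PAP85 by 0.39 (SE 0.12, adjusted p = 0.025), a call that was lost without Col-0 replicate 2 (adjusted p = 0.197) or without C24 replicate 1 or 2 (0.142 and 0.0939). Of the LEA genes 6 were higher, 2 lower and 14 not called (8 and 2 adjusted over the list alone, camera adjusted p = 0.472), with AT3G02480 at 1.31 (SE 0.24), LEA18 at 1.19 (SE 0.13) and AT2G23120 at -1.98 (SE 0.17). Of 5 measured seed coat genes 3 were called lower, BAN by -0.80 (SE 0.17), DFR by -0.68 (SE 0.10) and AT3G50990 by -2.14 (SE 0.16), while UGT80B1 at 0.04 and ARA12 at -0.23 were not called. The flavonoid list, with 2 of 3 lower and 2 adjusted over the list alone, had a camera adjusted p of 0.139. Of 4 cell division genes 3 were lower (3 lower and 1 higher adjusted over the list alone, 0.139), and the calls of AUR1 (-0.37, adjusted p = 0.049) and PRL (-0.40, adjusted p = 0.0418) were lost without single arrays of this stage, that of AUR1 also with a replicate block (0.059) and when scaled to the reference genes (0.0706). For AUR1 these were any Col-0 replicate or C24 replicate 1 or 2 (adjusted p from 0.0584 to 0.198), and for PRL Col-0 replicate 1 or 2 or C24 replicate 2 or 3 (0.107 to 0.154). The camera adjusted p of every list tested was 0.139 or above at this stage. The actin 3' to 5' log2 difference was 1.84 ± 0.21 in Col-0 and 0.85 ± 0.45 in C24 (SD, n = 3). That of GAPDH was 0.89 in Col-0 and 0.94 in C24, and that of ubiquitin 0.88 and 0.94.

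At 10-11 d, AT4G29200 and AT1G50290 led the genes higher in C24, with log2 differences of 5.48 (SE 0.19) and 4.40 (SE 0.14). The terpene synthase family gene AT1G48800 followed with 3.51 (SE 0.12), GSTU26, a glutathione transferase, with 3.21 (SE 0.10) and AT1G02300 with 2.94 (SE 0.15). The germin-like gene AT3G04200 was lower by -4.37 (SE 0.17), AT5G38180 by -4.32 (SE 0.54), the GDSL lipase family gene AT1G28590 by -4.12 (SE 0.18), AT1G23960 by -3.66 (SE 0.17) and the pectin methylesterase family gene AT5G51490 by -3.62 (SE 0.11). Limma adjusted p-values of these 10 were 5.2e-06 or lower. Photosynthesis genes were lower in C24, 4 of 8 called and 0 higher (5 adjusted over the list alone), LHCB4.2 by -0.75 (SE 0.13) and LHCB4.1 by -0.50 (SE 0.10), with a camera adjusted p of 0.0119 and adjusted p = 0.315 with an estimated correlation. Of 5 sucrose and starch genes 2 were lower (3 adjusted over the list alone), APL3 by -0.68 (SE 0.09), with a camera adjusted p of 0.0346 and adjusted p = 0.315 with an estimated correlation. Of the LEA genes 3 were higher and 2 lower, as when adjusted over the list alone (camera adjusted p = 0.9). In all 4074 probe sets were called, 2257 higher and 1817 lower, against 920 higher and 2406 lower when scaled to the reference genes. The actin 3' to 5' difference was 1.29 in Col-0 and 0.43 in C24, that of ubiquitin 0.52 and 0.91, and that of GAPDH 1.28 and 1.44.

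At 12-13 d, AT4G29200 was still higher in C24 by a log2 of 5.00 (SE 0.19) and AT1G50290 by 4.61 (SE 0.14), followed by the methyltransferase family gene AT5G38780 with 3.80 (SE 0.19), AT2G15960 with 3.60 (SE 0.14) and AT2G27570 with 2.99 (SE 0.13). AT4G20480 was lower by -4.42 (SE 0.20), AT1G17860, of the Kunitz inhibitor family, by -4.36 (SE 0.19), AT3G04200 by -4.20 (SE 0.17), AT1G23960 by -4.13 (SE 0.17), AT5G38180 by -4.05 (SE 0.54), AT4G14980 by -4.03 (SE 0.13), the pectin methylesterase family gene AT5G51500 by -3.93 (SE 0.17) and the LEA gene AT2G23110 by -3.73 (SE 0.18). Limma adjusted p-values of these 13 were 1.01e-05 or lower. Genes of plastid fatty acid synthesis were higher in C24, 6 of 10 called and 0 lower (8 adjusted over the list alone), AT5G16230 by 1.19 (SE 0.09) and AT4G16155 by 0.72 (SE 0.13), with a camera adjusted p of 0.00442 and adjusted p = 0.336 with an estimated correlation. OLEO3 was higher by 0.47 (SE 0.07) and BAN by 0.74 (SE 0.17). Of the LEA genes 0 were higher and 4 lower, as when adjusted over the list alone (camera adjusted p = 0.144). In all 5008 probe sets were called, 2781 higher and 2227 lower, against 1342 higher and 2367 lower when scaled to the reference genes. The 3' to 5' log2 difference was 0.93 in Col-0 and -0.28 in C24 for the actin control, 1.77 and 1.19 for GAPDH and 0.44 and 0.77 for ubiquitin.

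**Figure D4:**
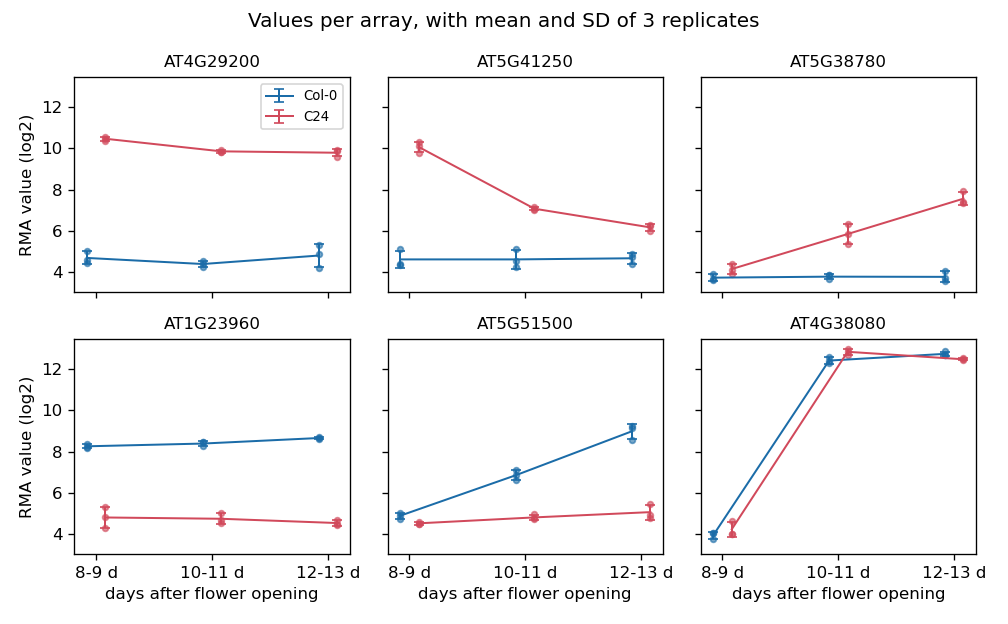
RMA log2 value against days after flower opening for 6 genes, with points for the arrays and lines and bars for the mean and SD of 3 replicates, Col-0 in blue and C24 in red. AT4G29200 lies at 9.79 to 10.47 in C24 at the 3 stages and at 4.38 to 4.79 in Col-0, and AT5G51500 rises in Col-0 from 4.88 to 8.98.

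Averaged over the stages, AT4G29200 was higher in C24 by a log2 of 5.42 (SE 0.11) and AT1G50290 by 4.35 (SE 0.08). AT5G38180 was lower by -4.30 (SE 0.31), AT4G20480 by -3.77 (SE 0.12) and AT1G23960 by -3.75 (SE 0.10). All 3 oil body genes were higher in C24 (3 adjusted over the list alone, camera adjusted p = 0.0897), and of 8 photosynthesis genes 1 was higher and 5 lower, also when adjusted over the list alone (0.0897). In all 7581 probe sets were called, 4557 higher and 3024 lower, against 2345 higher and 3652 lower when scaled to the reference genes. Before that scaling 2 of the 8 reference genes were themselves called higher in C24 and 1 lower (camera adjusted p = 0.968). The scaling therefore does not settle the direction of the accession differences. Of the 22746 probe sets 8698 (38.2%) were called at 1 or more stages. In 1215 the difference was called in the same direction at all stages, 607 higher and 608 lower in C24, where independent lists would share 46.0, and in 304 it was called in opposite directions at different stages.

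The change from 8-9 to 12-13 d differed between the accessions for several of these genes. AT5G51500 rose by a log2 of 4.11 in Col-0 and 0.54 in C24, a difference of -3.56 (SE 0.24, adjusted p = 2.56e-09). AT2G23110 rose by 5.14 and 1.60 (-3.54, SE 0.25), and AT4G14980 rose by 3.44 in Col-0 and was at 0.14 in C24 (-3.31, SE 0.18). AT1G62210 had the most negative difference, -4.61 (SE 0.51), with a rise of 5.08 in Col-0 and 0.47 in C24, not called there, and AT5G41250 fell by 3.91 in C24 and was at 0.05 in Col-0 (-3.97, SE 0.28). AT2G43535 rose by 3.39 in Col-0 and was at -0.15 in C24 (-3.54, SE 0.27). On the other side, AT2G15325 fell in Col-0 and was at -0.39 in C24, not called, a difference of 3.71 (SE 0.49). AT5G38780 rose by 3.42 in C24 and was at 0.04 in Col-0 (3.38, SE 0.27), the pectin methylesterase family gene AT1G11590 fell by 2.96 in Col-0 and was at 0.10 in C24 (3.06, SE 0.18), AT2G15960 had a difference of 2.94 (SE 0.20) and AT2G27570 of 2.83 (SE 0.19). The flat accession of such genes can lie low on the scale. AT5G51500 was at 4.46 to 5.47 on the C24 arrays and AT5G41250 at 4.21 to 5.10 on the Col-0 arrays. RMA may compress changes there, and for genes flat in C24, probes that differ from the C24 sequence are another possibility. Neither was tested for the interaction. In limma the interaction was called in 2080 probe sets, 900 higher and 1180 lower, against 463 higher and 1110 lower when scaled to the reference genes.

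Of 22 LEA genes 6 rose less in C24 by the interaction, 0 rose more and 16 were not called (6 lower adjusted over the list alone). AT3G02480 differed by a log2 of -1.38 (SE 0.33) and LEA18 by -1.03 (SE 0.18), and the camera adjusted p was 0.0306 and the adjusted p = 0.381 with an estimated correlation. AT3G17520 differed by -0.91 (SE 0.27, adjusted p = 0.038), a call lost with a replicate block (0.0502) and without Col-0 replicate 2 or C24 replicate 1 or 2 at 8-9 d, or Col-0 replicate 2 or 3 or any C24 replicate at 12-13 d (adjusted p from 0.0544 to 0.116). Of 3 flavonoid genes 2 fell less in C24 (2 adjusted over the list alone), BAN by 1.54 (SE 0.25) and DFR by 0.69 (SE 0.14), and UGT80B1 at -0.07 was not called, at a camera adjusted p of 0.0306 and adjusted p = 0.381 with an estimated correlation. Of the fatty acid genes 2 were higher and 1 lower (3 and 1 adjusted over the list alone), AT5G16230 by 0.85 (SE 0.13) and AT4G16155 by 0.74 (SE 0.18), at a camera adjusted p of 0.0455 and adjusted p = 0.381 with an estimated correlation, and of 0.0506 with a replicate block. AT3G50990 fell less in C24, by 2.09 (SE 0.22). AT1G03890 differed by -1.73 (SE 0.47, adjusted p = 0.0237), and the call was lost without C24 replicate 1 or 2 at 8-9 d (adjusted p = 0.0587 and 0.0634). AT3G02480, LEA18, AT3G17520 and AT1G03890 were higher in C24 at 8-9 d (1.31, 1.19, 0.73 and 1.83) and not called at 12-13 d. DFR and AT3G50990 were lower at 8-9 d (-0.68 and -2.14) and not called at 12-13 d. The interactions of these genes thus do not show different levels at 12-13 d. AT2G23110 instead was not called at 8-9 d and was at -3.73 at 12-13 d. BAN, AT5G16230 and AT4G16155 were called higher in C24 at 12-13 d.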

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

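The tests of the sign of the change by stage of the call, of the splits by the arrays they exchanged, and of the lean under reference gene scaling, were chosen only after the result was seen. A first set of results stands out because the change from 8-9 to 12-13 d differed between the accessions by a test of the interaction. It holds 2080 of 22746 probe sets (9.1%), and 33 of the 68 genes followed here. The rule for naming genes took some of these genes because the interaction called them, so their share is no further support. Of the gene lists, LEA proteins had a median interaction of -0.23 on the log2 scale, plastid fatty acid synthesis 0.26 and seed coat flavonoids 0.69, and each lost its call with an estimated correlation (adjusted p = 0.381), the fatty acid list also with a replicate block (0.0506). Genes with a lower change in C24 were AT1G62210 (-4.61), AT5G41250 (-3.97), AT5G51500 (-3.56), AT2G43535 (-3.54), AT2G23110 (-3.54), AT4G14980 (-3.31), CYP78A9 (-2.43), AT3G04200 (-1.84), AT1G03890 (-1.73), AT5G51490 (-1.46), AT3G02480 (-1.38), AT1G17860 (-1.25), AT1G02300 (-1.17), AT5G37670 (-1.10), AT4G20480 (-1.03), LEA18 (-1.03) and AT3G17520 (-0.91). Genes with a higher change in C24 were DFR (0.69), AT4G16155 (0.74), AT5G16230 (0.85), GSTU26 (0.95), JMT (0.97), AT4G15750 (1.303), AT1G48800 (1.304), BAN (1.54), AT4G15390 (1.87), AT2G32190 (2.09), AT3G50990 (2.09), AT2G27570 (2.83), AT2G15960 (2.94), AT1G11590 (3.06), AT5G38780 (3.38) and AT2G15325 (3.71).

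Other splits of the samples bear on these counts. For the accession difference averaged over the stages, 1 of 100 splits, the real one, gave as many probe sets, 7581 against 3871 in the highest other. Splits that mix the accessions count their difference as spread between arrays, which lowers their calls. Pools of a group could also share plants, so the real split stands out but chance is not excluded. For the interaction 5 of 100 splits, the real one included, gave 2080 or more, with 6724 in the highest other, so this count alone does not exclude chance. It also reads a structure of the samples. The split with 6724 exchanged the accession labels of all arrays at 12-13 d and of 0 at 8-9 d, and so reads the sum of the accession differences at these stages. The 24 splits, this one among them, that exchanged 0 or 3 arrays of an accession at a stage keep part of the accession difference and gave 487 to 6724 calls, and the 75 that exchanged 1 or 2 at both stages gave 0 calls each. Each comparison of 3 arrays with 3 has only 10 splits, too few for a share under 0.05. In each of them 1 of 10 splits, the real one, gave as many, with 4418 against at most 1 elsewhere for C24 minus Col-0 at 8-9 d, 4074 against 3 at 10-11 d and 5008 against 1 at 12-13 d. The steps gave 8403 against 1 and 7114 against 0 in Col-0, and 10058 against 1 and 5022 against 0 in C24, and the full interval gave 12330 and 12211 against 0 in both.

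The accession differences shared signs with the change over time, and on the first principal component C24 lay further along the axis of stage than Col-0 by 10.1 at 8-9 d and by 17.2 at 10-11 d (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allow) and at -1.20 at 12-13 d (p = 0.5, exact). The shares by sign were taken only over probe sets also called for the change in Col-0 from 8-9 to 12-13 d. Of 1315 probe sets called at 10-11 d only, 956 were left, and 86.2% of these had the sign of that change (exact 95% interval 83.8 to 88.3). The intervals here treat probe sets as independent, which they are not, so they do not measure the spread between pools. C24 seeds of the 10-11 d window may thus have been further along the same course. Across all probe sets the correlation was weaker, with Pearson's r of 0.259. Of 1215 called in one direction at all stages 865 were left, and 60.5% of these had that sign (57.1 to 63.7). These values do not settle whether timing is a part of the accession differences. Of probe sets called at 8-9 d only 75.0% of 1240 had that sign and of those at 12-13 d only 19.5% of 1503, but these classes share Col-0 arrays with the change, which alone pulls the shares in those directions. Since siliques of 10 and 11 days were pooled in shares that are not given, a difference in sampling and a difference in pace between the accessions both stay open.

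Large accession differences leaned toward a lower signal in C24. Of 63 probe sets with an averaged difference of at least 4-fold 66.7% were lower in C24 (exact 95% interval 53.7 to 78.0, which treats probe sets as independent). Between 2-fold and 4-fold 57.7% of 281 were lower, and under 2-fold 39.0% of 7237. Probes designed on another sequence than that of C24 could give such a lean, and single genes such as AT1G23960, lower in C24 at every stage, may be read that way or as a real difference. Scaled to the reference genes, the shares were 69.4% at 4-fold or more and 60.5% under 2-fold, so the contrast with small differences rests on the scaling, which moves all probe sets alike by -0.07 and could hardly turn the large ones. A part of dim probe sets near the floor stays open, since keeping those whose brighter accession averaged 6 or more left 61 of the 63 (67.2% lower) and so decides nothing; probe sequences of C24 were not used here.

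The source name field of every sample gives the other accession than its title. If the titles were exchanged and the probes come from the Col-0 genome, the large differences should be mostly lower in the samples titled Col-0, and 33.3% were. This argues against exchanged titles, under that premise about the array and as far as sequence differences shape these signals. A biological difference in level between the accessions was not tested as a cause of the lean.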

How the results depend on the processing

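The shares of lower signal by size under reference gene scaling were chosen only after the result was seen. No called difference of a named gene or gene list changed sign under any alternative run on it, but some of these could not change a sign. For named genes the replicate block and the filter on dim probe sets leave log2 differences as they are. Only reference gene scaling and leaving out arrays could reverse one. For gene lists an estimated correlation leaves the direction as it is. The majority direction of the calls did change under reference gene scaling, in the averaged accession difference (from 4557 higher and 3024 lower to 2345 and 3652), at 10-11 and 12-13 d and in other comparisons as given with them, and the share lower in C24 under 2-fold went from 39.0% to 60.5%. It also changed with quantile normalization at 10-11 d (1981 higher and 2017 lower), with 1 probe set per gene in the full interval of Col-0 (3343 and 3293) and C24 (3388 and 3292), with 1851 each way in the second step of Col-0, and without Col-0 replicate 1 at 12-13 d in the full interval of Col-0 (6087 and 6049). With a 2-fold minimum it changed at 8-9 d (246 and 253), 10-11 d (211 and 253) and 12-13 d (190 and 326), in the average (140 and 204) and in the first step of Col-0 (873 and 858). In number of calls, scaling to reference genes, quantile normalization, the filter on dim probe sets, leaving out shared probe sets, the trend and robust variance, array weights and fitting only the groups compared each left every count of called probe sets within 1.5 times its value. In the order C24 minus Col-0 at 8-9, 10-11 and 12-13 d and averaged, then the first step, second step and full interval in Col-0 and in C24, then the interaction, 1 probe set per gene gave 2370, 2151, 2675, 4111, 4368, 3702, 6636, 5413, 2568, 6680 and 1004 calls, all also called before, because 13286 loci were tested. A 2-fold minimum gave 499, 464, 516, 344, 1731, 950, 3443, 1893, 580, 3076 and 483, by its construction. With an estimated correlation 11 calls of gene lists were made over the 11 comparisons against 36 with the preset one. The correlation of the changes of the accessions was 0.937 without dim probe sets against 0.925; the cause was not tested. Leaving out each array in turn gave, in the same order, 3315 to 4221, 2936 to 3644, 3997 to 4922, 7000 to 7647, 7242 to 7835, 5573 to 7289, 11387 to 12136, 8860 to 9475, 3965 to 4652, 11004 to 11672 and 1617 to 2126 calls, and r of 0.918 to 0.925. A set of 184 results held those of named genes and the shares lower in C24 by size. Of these 13, all of named genes, lost their call in at least 1 setting, and 0 results of named genes reversed in any. The main fit did not pair samples by replicate number. Correlations of deviations between arrays of the same number lay between -0.156 and 0.200, and 0 comparisons had all 3 pairs above 0.1. With 3 arrays per group this does not exclude plants or processing shared between arrays of the same number. A replicate block gave 4455, 4093, 5095, 7644, 8464, 7192, 12391, 10164, 5060, 12282 and 2052 calls, and 35 calls of gene lists. Signals near 3 or 4 lie at the floor of the scale, where differences are compressed.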

Other observations

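The test of mitochondrial transcripts in this part was chosen only after the result was seen, while that of neighbouring genes was not. Transcripts of the plastid genome, a set chosen after seeing the data, were lower in C24. Camera p-values of the plastid and mitochondrial sets are adjusted over these sets alone, not over the 12 lists. Of 69 plastid probe sets 38 were lower and 7 higher in the averaged accession difference, with a median log2 of -0.37 (camera adjusted p = 4.75e-07, and adjusted p = 0.184 with an estimated correlation). At 10-11 d 30 were lower and 2 higher (median -0.45), at 12-13 d 22 and 5 (median -0.40), and at 8-9 d 5 and 7 (median -0.13, camera adjusted p = 0.208). The actin 3' to 5' log2 difference, a sign of RNA quality, was lower in C24 at each stage, at 0.85, 0.43 and -0.28 against 1.84, 1.29 and 0.93 in Col-0, and that of ubiquitin was 0.91 and 0.77 against 0.52 and 0.44 at 10-11 and 12-13 d. That of GAPDH was 0.94, 1.44 and 1.19 in C24 against 0.89, 1.28 and 1.77 in Col-0, so the controls did not all move in the same direction. In Col-0 16 of 23 mitochondrial probe sets rose from 8-9 to 12-13 d (camera adjusted p = 0.00108, adjusted p = 0.362 with an estimated correlation), and in C24 15 rose. If organelle transcripts as a class gave less signal in C24, mitochondrial ones should be lower too, but their median averaged difference was -0.0292 over 23 probe sets, with 5 called higher and 5 lower. Several of the 23 report on the same gene, nad1, with probe sets called lower (-0.50 and -0.31) and higher (0.41), so these are not counts of separate genes. Members spread with an SD of 0.36, and the plastid median lies at -0.34 relative to theirs, so this does not decide whether the class was lower. Why plastid transcripts were lower stays open, and the lower photosynthesis genes at 10-11 d were nuclear genes.

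Neighbouring genes tended to differ in the same direction. Of 612 pairs of neighbouring loci, both called for the averaged accession difference, 59.3% had one direction, against a median of 51.8% and a middle 95% of 47.7 to 55.7% in 10000 shuffles (one-sided permutation p = 2e-04). A candidate explanation is stretches of the genome that differ as a unit between the accessions, with tandem copies that share probes as another that this test does not exclude.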
